A study of Bos taurus with 8 samples.

How the data were processed

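Gene expression was measured on 8 one-colour Agilent bovine arrays, each hybridised with total RNA of 1 sample labelled with the dye Cy3. Per the labels, RNA was purified on silica columns with a DNase step, copied with an oligo-dT primer and amplified by in vitro transcription with the Agilent Quick-Amp kit. The labels name cattle as the organism, while their protocol text says that the tissue came from buffalo, so the RNA is buffalo RNA on cattle probes as far as the protocol goes. Samples were grouped by the pregnancy status in the labels, with 4 arrays labelled non-pregnant and 4 labelled pregnant. The same labels call every sample fetal cotyledon (the fetal side of the ruminant placenta) of female sex and describe every sample as taken before pregnancy. Because measured placental and uterine transcripts go against the group labels, the groups are called arrays labelled pregnant and arrays labelled non-pregnant throughout.

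The spot intensity values deposited by the authors are scanner output that, per the file headers, was made with Agilent Feature Extraction 11.5.1.1 under the protocol GE1_1105_Oct12. Per the file headers, the processed intensity of a spot has its local background and a spatial trend subtracted and is not scaled between arrays. The flags deposited in the same files mark spots well above background, saturated spots and spots with uneven or outlying pixels, as 0 or 1 per spot. The authors also deposited a table of log2 values, which correlated with log2 of the processed intensity of the same array at r = 0.999 or above and had a 75th percentile near 0 in each array. That scale and centring were read from the values, since the sources used here do not state them, and no centring per probe was seen. The medians of its 8 columns were -4.21, -4.01, -4.00 and -3.77 for the arrays labelled non-pregnant and -3.56, -3.61, -3.64 and -3.61 for those labelled pregnant.

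For the values reported here, log2 of the processed intensity was taken and the array's own 75th percentile was subtracted. The 1319 control spots of each array were left out, as were the 119 spots with an outlier flag, and no spot was saturated. Spots of 1 probe were averaged, which concerned 10275 of the 51282 probes on 61657 spots. A probe counted as well above background on an array when at least 0.5 of its spots had that flag. The 34630 probes well above background on at least 4 of the 8 arrays, whatever their group, were tested.

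Gene names came from the scanner files and from a table of cattle reference genes (assembly ARS-UCD2.0), used for names only. The accession in the file matched that table for 28112 probes, another accession of the probe for 1772, the file's symbol for 5521 and a synonym for 159. The file's own name was kept for 15716 probes, and 2 probes matched several genes. In all, 34659 probes carried a gene symbol, for 16376 symbols, of which 12883 had a tested probe. Probe coordinates are those of the scanner files, whose headers name the build Btau_3.1. Whether a probe lies in an exon, an intron or an untranslated region is not given in the sources used here. Many probes stand for families of near-identical genes, such as pregnancy-associated glycoproteins, prolactin-related proteins, globins and histocompatibility genes, and their signals can include related copies.

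Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 8 arrays, no covariates), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Differences are log2 values of the arrays labelled pregnant minus those labelled non-pregnant, with their standard error (SE), and n is 4 arrays per group. A gene was represented by its tested probe with the highest mean signal over all 8 arrays. Counts at 2-fold add a log2 difference of at least 1 in size. Where a probe was well above background on no array of a group, its change is a bound, written as at least N-fold. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. It equals the fitted difference where the probe's own signal was the higher on every array of the dim group, as for ESR1 and FGG. A bound holds only under the main background and scaling. TP63, at least 4.92-fold lower, gave a log2 difference of only -0.35 with the alternative normexp background correction. Where a probe was well above background on some arrays of a group, their number is given with the fitted difference.

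Lists of genes were written before the data were examined, as were the tests, the filter, the rule for naming genes and the alternatives, except where a choice is said to have come later. There were 30 lists with at least 5 tested members and a shorter list of sex-linked genes. They covered trophoblast secreted products, trophoblast transcription factors and identity genes, simple epithelium, steroid hormone synthesis and metabolism, cholesterol synthesis, imprinted genes, endometrium, smooth muscle, endothelium, angiogenic factors, leukocytes, interferon-stimulated genes, class I antigen presentation, collagens and matrix, matrix proteases, erythroid cells, cell cycle and nutrient transporters. The others were the prostaglandin pathway, the insulin-like growth factor system, glycolysis and hypoxia, inflammatory cytokines, immediate early and heat shock genes, liver and yolk sac plasma proteins, allantoic and amniotic membrane candidates, ribosomal proteins, the respiratory chain, endoplasmic reticulum stress, antioxidant enzymes and reference genes.

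Each list was set against all other tested genes with camera of limma, two-sided, at a preset correlation between genes of 0.01, with adjustment over the 30 lists. The 13 genes with a missing value on any array were left out of these tests. The same test with an estimated correlation and the rotation test fry were run as alternatives. Members of a list that passed the threshold are counted over all genes tested and, where the count differs, adjusted over the list alone. The share of probes well above background and the brightness of the arrays were compared with two-sided exact permutation tests over 70 arrangements, for which the smallest possible p is 0.0286.

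The genes named are the 10 largest differences per direction among genes with adjusted p below 0.05, no overlap between groups, signal well above background on all 8 arrays and an informative symbol. Added to these are the 5 largest bounds per direction, up to 4 members of each list with the largest difference past the threshold, and a fixed set made of CSH2, PAG1, PAG2, PRP1, SERPINA14, PGR, ESR1 and XIST. PAG1 had no tested probe. The values of some single list members are not reported here. Further list members are named as exceptions or as members that did not pass, and were chosen after their values were seen.

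Alternatives were normexp background correction (offset 50) of mean and background intensity, quantile normalization, scaling by the median or by the 75th percentile over probes above background on all arrays, and no scaling. Others were no filter or a strict filter (all 8 arrays) on dim probes, outlier spots kept, eBayes with trend and robust, array weights, the replicate number as a fixed or random block, the mean of all probes of a gene, the authors' log2 values, treat in place of the 2-fold filter, and each array left out in turn. A fit without labelled non-pregnant array 3 and labelled pregnant array 4 was added after seeing the data. All arrays lay on 1 slide with 1 scan, so neither could be tested as a batch. Each group filled 1 of the 2 lines of arrays on the slide, so position on the slide and group cannot be told apart.

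The scripts were tested on simulated data for the comparison of labelled pregnant with labelled non-pregnant arrays, with 200 of 34599 probes changed. Of the probes changed by 1 on the log2 scale, 13 of 67 (19.4%) were recovered, of those changed by 2, 46 of 67 (68.7%), and of those changed by 4, 62 of 66 (93.9%). There were 9 calls on unchanged probes. In the data, 20563 of 34630 tested probes were called, so the adjustment was less strict there. The recovered shares therefore do not give the sensitivity of the real comparison. In a simulation of 12878 genes with the cell cycle list shifted by 1, that list was called and 0 of the 29 others were. Genes were simulated independently of each other, so this cannot check the list calls where genes of a list vary together. The number of arrays limits the precision of every value.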

Results

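Messenger RNA was profiled on 8 bovine arrays of 51282 probes, 4 from samples labelled non-pregnant and 4 from samples labelled pregnant, all named as fetal cotyledon. The series title speaks of expression differences between fetal cotyledons, and the only comparison that the labels allow is the one by pregnancy status. Between 63.7% and 69.5% of probes were well above background on the arrays labelled non-pregnant and between 60.6% and 66.0% on those labelled pregnant. The group means were 66.0% ± 2.78 and 63.7% ± 2.32 (SD, n = 4 each), a difference of -2.29 points (exact permutation test, two-sided, p = 0.257). The 75th percentile of the spot intensity was 1168, 1558, 1246 and 1797 on the arrays labelled non-pregnant and 798, 970, 1019 and 1347 on those labelled pregnant. On the log2 scale it averaged 10.47 ± 0.29 against 9.99 ± 0.31 (SD, n = 4 each; exact permutation test, two-sided, p = 0.0857, where 0.0286 is the smallest possible). Over all tested probes, arrays correlated at 0.957 to 0.987 among those labelled non-pregnant, at 0.943 to 0.989 among those labelled pregnant and at 0.736 to 0.783 between the groups. Labelled pregnant array 4 stood apart from its group, at 0.943 to 0.951 against at least 0.977 among the other 3. No label says that the replicates came from separate animals, so p-values measure only the spread between these samples, part of which may be technical.

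The arrays labelled non-pregnant carried higher signals of placental hormones, fetal globin and cell cycle genes, and the arrays labelled pregnant carried uterine, immune and interferon-responsive transcripts in their place. CSH2, the placental lactogen made by ruminant trophoblast, averaged 6.98 ± 0.41 on the arrays labelled non-pregnant and -1.41 ± 1.43 on those labelled pregnant (log2 signal relative to the array's 75th percentile, SD, n = 4 each). The progesterone receptor PGR, expressed in the uterus, averaged -6.34 ± 0.26 and 1.79 ± 1.06 in the same order. These directions go against the group names, since placental products would belong with pregnancy, so every direction in this text refers to the labels and not to a known state of the tissue. In limma, 8063 of 12883 genes (62.6%) differed at an adjusted p below 0.05, 3828 higher and 4235 lower in the arrays labelled pregnant. Of these, 6180 differed at least 2-fold, 3056 higher and 3124 lower. Without labelled non-pregnant array 3 and labelled pregnant array 4, a choice made after seeing the data, 8035 genes differed. The 4 values of a group did not overlap those of the other for 7766 genes (60.3%), where chance separates 2.86% of splits. Among called genes, 47.5% were higher and 52.5% lower, a split that depended on the processing and became 34.8% and 65.2% with median scaling and 31.4% and 68.6% without scaling. More than 50% were higher with the percentile over detected probes (53.8%), without the filter on dim probes (54.95%), with quantile normalization (50.6%) and with normexp (50.1%). The median difference of all genes was -0.03, and it was -0.42 with median scaling, -0.51 without scaling, 0.14 with the percentile taken over probes detected on all arrays and 0.22 without the filter on dim probes. Of 7530 genes with several tested probes, 180 called genes had another probe called in the opposite direction. Every stated difference below is labelled pregnant minus labelled non-pregnant on the log2 scale with n = 4 per group.

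**Figure D1:**
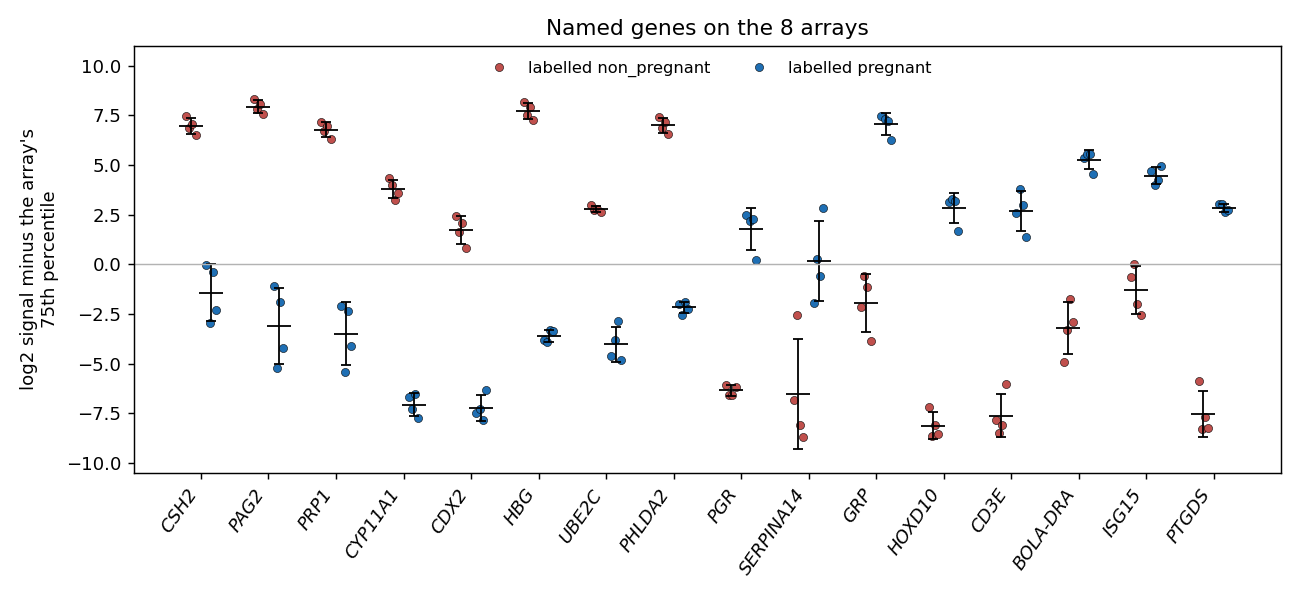
Signal of 16 named genes on each of the 8 arrays (y axis, log2 signal minus the array's 75th percentile), with 1 point per array and the mean and SD of each group of 4. CSH2 averaged 6.98 on the arrays labelled non-pregnant and -1.41 on those labelled pregnant, while PGR averaged -6.34 and 1.79.

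Secreted trophoblast products, the hormones and glycoproteins that the ruminant placenta releases into the mother, were lower in the arrays labelled pregnant for 29 of 30 tested genes and not called for TKDP2 (-1.34, SE 1.09, measured on 3 of 4 arrays of each group). The pregnancy-associated glycoproteins led, a placental family related to aspartic proteases. PAG2 (chromosome 29, 39312070 to 39312129) differed by -11.04 (SE 0.82, adjusted p = 6.92e-06) and was well above background on 3 of 4 arrays labelled pregnant. PAG11 differed by -10.95 (SE 0.47), PAG6 by -10.60, PAG17 by -10.58, PAG4 by -9.65 and PAG7 by -9.16, all well above background on all 8 arrays. PAG12, at -12.79 (SE 0.69), was well above background on 1 of 4 arrays labelled pregnant, PAG8 at -12.11 (SE 0.85) on 3 and PAG16 at -11.95 (SE 0.66) on 2. PAG18 was at least 2005-fold lower (adjusted p = 4.66e-08). The prolactin-related proteins PRP1 (chromosome 23, 35000518 to 35000577; -10.28, SE 0.69, measured on 3 of 4 arrays labelled pregnant) and PRP3 (-11.75, SE 0.42, measured on 1 of 4) fell with CSH2 (chromosome 23, 35539720 to 35539778; -8.39, SE 0.63, adjusted p = 7.38e-06). SSLP1 gave -8.98 (SE 0.75) on its brightest probe, but its other 2 tested probes were called in the opposite direction, and leaving out any array labelled non-pregnant made another probe the brightest, with differences of 1.20 to 1.502. The list median was -10.32 (-10.17 with 5 members at their bound; camera adjusted p = 1.05e-13, adjusted p = 0.265 with an estimated correlation).

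Transcription factors and identity genes of trophoblast followed, with 15 of 21 lower, 1 higher and 5 not called. CDX2, a regulator that specifies trophectoderm, was at least 398-fold lower (adjusted p = 6.93e-07), and PLAC1, a placental membrane protein, at least 140-fold lower (adjusted p = 2.40e-07). HAND1 (-7.52, SE 0.27) and PPARG (-6.44, SE 0.31), both needed for placental development, fell on probes measured on all arrays. ELF5, another trophoblast factor that other epithelia also express, went the other way (3.03, SE 0.95, adjusted p = 0.0220). The median of these factors was -2.90 (camera adjusted p = 3.36e-05, adjusted p = 0.265 with an estimated correlation). Simple epithelium genes were lower for 12 of 20 (13 adjusted over the list alone) and higher for 0, led by the splicing regulators ESRP2 (-3.15, SE 0.21) and ESRP1 (-2.66, SE 0.41), the recycling GTPase RAB25 (-3.10, SE 0.29) and the tight junction protein CLDN7 (-2.51, SE 0.39). The epithelial markers EPCAM (-0.67, SE 0.42), KRT18 (-0.24, SE 0.37) and KRT7 (1.101, SE 0.54) did not pass. The epithelial median was -1.76 (camera adjusted p = 0.00203, adjusted p = 0.442 with an estimated correlation). Labelled pregnant array 4 lay apart from the mean of the other 3 by -1.56 in the median of the trophoblast factors and by 1.79 in that of the epithelial genes. Its epithelial median of 2.54 lay within the range of the arrays labelled non-pregnant (2.23 to 2.80), so the fall of that median was not seen on array 4.

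Enzymes of steroid hormone synthesis and metabolism were lower for 13 of 26 genes (15 adjusted over the list alone), higher for 6 and not called for 7. CYP11A1, which makes pregnenolone from cholesterol (chromosome 21, 34419770 to 34419829), was at least 1478-fold lower (adjusted p = 1.18e-07), and the steroid sulfatase STS at least 103-fold lower (adjusted p = 1.34e-06). The estrogen sulfotransferase SULT1E1 differed by -11.48 (SE 0.55, measured on 2 of 4 arrays labelled pregnant) and HSD3B1, which makes progesterone, by -9.43 (SE 0.64, measured on 1 of 4). HSD11B1, which regenerates active glucocorticoid, rose by 3.17 (SE 0.68). The steroid median was -1.32 (camera adjusted p = 0.0301, adjusted p = 0.379 with an estimated correlation), and the call ended without scaling (-1.81, adjusted p = 0.0682) and with the strict filter on dim probes (-0.96, adjusted p = 0.297), within a range of 0.00614 to 0.297 over 23 alternatives. In that median, labelled pregnant array 4 lay apart from the mean of the other 3 by 1.16. Cholesterol synthesis was lower for 17 of 21 genes and higher for 0, with PMVK at -2.56 (SE 0.33), NSDHL at -2.52 (SE 0.46) and SC5D at -2.36 (SE 0.20). Its median was -1.77 (camera adjusted p = 0.000287, adjusted p = 0.442 with an estimated correlation).

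Imprinted genes, expressed from 1 parental copy and often active in placenta, were lower for 12 of 20, higher for 2 and not called for 6. PHLDA2, which restrains placental growth (chromosome 29, 50555887 to 50555946), averaged 6.997 ± 0.36 on the arrays labelled non-pregnant and -2.16 ± 0.29 on those labelled pregnant (SD, n = 4 each; adjusted p = 6.32e-08). DLK1 (-7.03, SE 0.26), PEG3 (-4.69, SE 0.29) and NAP1L5 (-4.04, SE 0.31) fell as well, while NDN (3.11, SE 0.30) rose. MAGEL2 gave 1.05 (SE 0.30) on its brightest probe, with 1 of its other 3 tested probes called lower. The growth factor gene IGF2 (-0.34, SE 0.20, with 1 of its other 12 tested probes called higher) and the long noncoding RNA H19 (-1.40, SE 0.72) did not pass. Over the imprinted genes the median was -1.50 (camera adjusted p = 0.00896, adjusted p = 0.442 with an estimated correlation).

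Erythroid genes were lower in the arrays labelled pregnant for 11 of 17, higher for 1 and not called for 5. The fetal globin HBG (chromosome 15, 47886299 to 47886358) averaged 7.73 ± 0.40 and -3.58 ± 0.30 (SD, n = 4 each; -11.31, SE 0.25, adjusted p = 4.14e-08). HBB (chromosome 15, 47825720 to 47825779) was at least 1944-fold and HBM at least 353-fold lower (adjusted p = 4.66e-08 and 7.52e-07), and HBA differed by -8.26 (SE 0.56). The globin probes can read related globins. The erythroid median was -3.39 (camera adjusted p = 0.000464, adjusted p = 0.265 with an estimated correlation), and with the strict filter on dim probes, which removes members dim in a group, it was -0.54 (adjusted p = 0.116; 5.45e-05 to 0.116 over 23 alternatives). In that median, labelled pregnant array 4 lay apart from the mean of the other 3 by 0.95. Genes of the cell cycle were lower for 28 of 29 (29 adjusted over the list alone), with CDC20 at -7.29 (SE 0.52) and RRM2 at -6.77 (SE 0.66), each measured on 3 of 4 arrays labelled pregnant, UBE2C at -6.80 (SE 0.40) and CDC6 at least 70.9-fold lower (adjusted p = 1.89e-07). Their median was -5.34 (camera adjusted p = 1.32e-11, adjusted p = 0.265 with an estimated correlation), between -5.82 and -3.14 over 6 scalings and backgrounds. Glycolysis and the hypoxia response were lower for 18 of 23 genes and higher for 2, with the hypoxia-inducible lipid droplet gene HILPDA at least 26.4-fold lower (adjusted p = 8.53e-07), PDK1 at -4.95 (SE 0.24), LDHA at -3.35 (SE 0.24) and PFKP at -3.15 (SE 0.31). The genes that rose were DDIT4 (0.96, SE 0.23) and EGLN3 (0.75, SE 0.27), both hypoxia-inducible. The glycolysis and hypoxia median was -1.67 (camera adjusted p = 5.79e-05, adjusted p = 0.265 with an estimated correlation).

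Genes of the endometrium, the lining of the uterus, were higher in the arrays labelled pregnant for 15 of 23, lower for 1 (MSX1, -1.05, SE 0.30) and not called for 7. HOXD10, a homeobox gene of the posterior body and reproductive tract (chromosome 2, 21457902 to 21457961), was at least 1604-fold higher (adjusted p = 3.50e-07). GRP, a secreted peptide of uterine glands (chromosome 24, 60582286 to 60582345), averaged -1.93 ± 1.45 and 7.07 ± 0.54 (SD, n = 4 each; 9.004, SE 0.65, adjusted p = 6.07e-06). PGR (chromosome 15, 6522430 to 6522489) differed by 8.13 (SE 0.47, adjusted p = 1.96e-06) and SERPINA14, the uterine milk protein (chromosome 21, 59392443 to 59392502), by 6.69 (SE 1.41, adjusted p = 0.00314), each well above background on 1 of 4 arrays labelled non-pregnant. The estrogen receptor ESR1 was at least 14.5-fold higher (adjusted p = 9.25e-06). The gland genes PAEP (-0.11, SE 0.18) and FOXA2 (0.33, SE 0.23, measured on 2 of 4 arrays labelled pregnant) did not pass. Over the endometrial genes the median was 3.61 (camera adjusted p = 0.000118, adjusted p = 0.265 with an estimated correlation).

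Smooth muscle genes were higher for 8 of 17, lower for 2, among them TPM1 (-1.78, SE 0.25, with 3 of its other 8 tested probes called higher), and not called for 7. The calcium pump regulator PLN was at least 24.9-fold higher (adjusted p = 6.80e-05), and the contractile and cytoskeletal genes LMOD1 (4.15, SE 0.36), DES (3.41, SE 0.21) and TAGLN (2.64, SE 0.46) rose. ACTG2 (-1.78, SE 0.90) and MYH11 (-0.76, SE 0.57), abundant in visceral muscle, did not pass. The smooth muscle median was 0.86 (camera adjusted p = 0.0396, adjusted p = 0.442 with an estimated correlation). That call ended with normexp (adjusted p = 0.0524), the percentile over detected probes (0.0511), no filter (0.0672), the strict filter (0.0605), without labelled non-pregnant array 4 (0.0536) and without labelled pregnant array 3 (0.0555). It also ended without both labelled non-pregnant array 3 and labelled pregnant array 4 (0.0534), a fit chosen after seeing the data. The adjusted p lay within 0.00740 to 0.0672 over 23 alternatives. Endothelial genes went both ways, with 7 of 19 higher and 4 lower, among them VWF at 5.82 (SE 0.22), ENG at 2.97 (SE 0.34), MMRN2 at 2.39 (SE 0.18) and the receptor FLT1 at -3.68 (SE 0.67, measured on 2 of 4 arrays labelled pregnant). Their median was 0.53 (camera adjusted p = 0.168), between 0.04 and 0.69 over the scalings. Angiogenic factors and receptors were higher for 8 of 26 and lower for 6, with THBS1, an inhibitor of vessel growth, at 3.41 (SE 0.78), EDN1 at 2.35 (SE 0.36) and the endothelin receptor EDNRB at least 10.1-fold lower (adjusted p = 3.73e-05). The angiogenic median of 0.32 (camera adjusted p = 0.427) changed sign over the scalings, from -0.16 to 0.49.

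Leukocyte genes were higher in the arrays labelled pregnant for 18 of 24, lower for 2 and not called for 4. The CD3 chains of the T cell receptor complex, CD3E (10.30, SE 0.63, well above background on 1 of 4 arrays labelled non-pregnant) and CD3G (at least 192-fold, adjusted p = 1.46e-05), rose. So did the class II chain BOLA-DRA (chromosome 23, 26439544 to 26439586; 8.48, SE 0.59) and its chaperone CD74 (6.43, SE 0.40, measured on 2 of 4 arrays labelled non-pregnant). Among genes of monocytes and macrophages, CD14 (2.65, SE 0.36) and CD68 (1.65, SE 0.31) rose, AIF1 (-3.09, SE 0.35) and CSF1R (-1.93, SE 0.26) fell, and CD163 (0.76, SE 0.69, measured on 3 of 4 arrays labelled pregnant) did not pass. The pan-leukocyte gene PTPRC gave 0.01 (SE 0.36). Leukocyte genes had a median of 3.07 (3.04 with 3 members at their bound; camera adjusted p = 4.98e-05, adjusted p = 0.442 with an estimated correlation). Labelled pregnant array 4 lay apart from the mean of the other 3 by -1.33 in the leukocyte median. Interferon-stimulated genes, which many cells switch on in response to interferons, rose for 23 of 26 (24 adjusted over the list alone) and fell for 0. The antiviral genes OAS2 (6.57, SE 0.60) and RSAD2 (6.502, SE 0.56), each well above background on 1 of 4 arrays labelled non-pregnant, OAS1Y (6.42, SE 0.50) and the ubiquitin-like modifier ISG15 (5.76, SE 0.55) led. Their median was 2.63 (camera adjusted p = 9.32e-09, adjusted p = 0.265 with an estimated correlation).

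Class I antigen presentation was higher for 12 of 17 genes and lower for 3. The classical and non-classical class I genes BOLA (5.42, SE 0.75) and BOLA-NC1 (6.59, SE 1.16), the transcription factor IRF1 (4.63, SE 0.21) and the immunoproteasome subunit PSMB10 (4.29, SE 0.20) rose, whereas the chaperones CALR (-1.06, SE 0.26), PDIA3 (-0.99, SE 0.34) and CANX (-0.75, SE 0.21), which fold many secreted proteins, fell. The list median was 2.81 (camera adjusted p = 0.000391, adjusted p = 0.422 with an estimated correlation). Inflammatory cytokines and acute phase genes were higher for 17 of 24 and lower for 2, with the chemokines CCL5 (chromosome 19, 13977535 to 13977591; 9.33, SE 0.79), CXCL12 (5.36, SE 0.78, measured on 3 of 4 arrays labelled non-pregnant), CXCL5 (at least 64.4-fold, adjusted p = 0.00110) and CXCL2 (at least 36.0-fold, adjusted p = 0.000208). The probe named CXCL5 is described as CXCL6 in its annotation, and its signal ran from -5.47 to 0.52 over the arrays labelled pregnant. The cytokine IL6 was at least 19.8-fold lower (adjusted p = 0.000157) and the pattern recognition protein PTX3 differed by -3.96 (SE 0.59, measured on 3 of 4 arrays labelled pregnant). The inflammatory median was 2.95 (camera adjusted p = 0.000353, adjusted p = 0.422 with an estimated correlation). In these medians, labelled pregnant array 4 lay apart from the mean of the other 3 by -1.04 (class I) and -1.56 (inflammatory).

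Collagens and matrix genes were higher for 13 of 25, lower for 1 (the basement membrane collagen COL4A1, -1.14, SE 0.17) and not called for 11. TNC (5.85, SE 1.16, measured on 3 of 4 arrays labelled non-pregnant), FBLN1 (4.30, SE 0.31), COL15A1 (3.94, SE 0.45) and COL6A1 (3.33, SE 0.31) rose, while the abundant COL1A1 (0.63, SE 0.39) and FN1 (-0.22, SE 0.41) did not pass. The list median was 1.03 (camera adjusted p = 0.00474, adjusted p = 0.502 with an estimated correlation), between 0.55 and 1.20 over the scalings. Matrix proteases and inhibitors were higher for 14 of 26 and lower for 8, with the lysosomal protease CTSL at -8.68 (SE 0.53), the heparan sulfate cleaving enzyme HPSE at -6.23 (SE 1.14, measured on 1 of 4 arrays labelled pregnant), MMP7 at 6.51 (SE 0.41) and ADAMTS5 at 5.56 (SE 0.60). The protease median was 1.65 (camera adjusted p = 0.0827), and the list passed with median scaling (adjusted p = 0.0262), without scaling (0.0150) and with the mean of all probes (0.0467), within 0.0150 to 0.145 over 23 alternatives.

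In the prostaglandin pathway, 10 of 18 genes were higher and 4 lower. The prostaglandin D synthase PTGDS rose by 10.39 (SE 0.50, well above background on 1 of 4 arrays labelled non-pregnant) and the receptor PTGER2 was at least 34.6-fold higher (adjusted p = 1.01e-05), while the receptor PTGER3 (-5.77, SE 0.31) and the carrier SLCO2A1 (-4.30, SE 0.34), each measured on 1 of 4 arrays labelled pregnant, fell. The list median was 1.55 (camera adjusted p = 0.210). The insulin-like growth factor system split too, with 8 of 18 higher and 6 lower. The RNA-binding proteins IGF2BP1 (at least 901-fold, adjusted p = 4.14e-08) and IGF2BP3 (-7.83, SE 0.28), which are mostly fetal, were lower, while the binding protein IGFBP6 (6.01, SE 0.31) and the growth hormone receptor GHR (5.61, SE 0.39) were higher. Its median of 0.15 and mean of -0.03 differed in sign (camera adjusted p = 0.702), the rotation test fry called it lower (adjusted p = 0.000806), and the median ranged from -0.33 to 0.48 over the scalings.

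Nutrient transporters were higher for 11 of 36 and lower for 16. The taurine carrier SLC6A6 (-6.83, SE 0.45) and the fatty acid receptor CD36 (-6.40, SE 0.47), each measured on 3 of 4 arrays labelled pregnant, and the fatty acid carrier SLC27A6 (at least 55.5-fold, adjusted p = 5.07e-06) were lower, and the glutamate carrier SLC1A1 was higher by 6.65 (SE 1.01). Their median was -0.49 (camera adjusted p = 0.395). Immediate early and heat shock genes, which respond to handling and stress, were higher for 8 of 25 and lower for 4, with DUSP2 at 4.13 (SE 0.57, measured on 1 of 4 arrays labelled non-pregnant), KLF2 at 2.43 (SE 0.47), HSPB1 at 2.19 (SE 0.18) and EGR1 at 2.08 (SE 0.46). That median of 0.42 (camera adjusted p = 0.210) ranged from -0.06 to 0.85 over the scalings. Over its members, labelled pregnant array 4 had a median signal of 2.14, against 2.86 to 3.36 in the other 3 and 1.73 to 2.38 in the arrays labelled non-pregnant. Plasma protein genes of liver and yolk sac were higher for 5 of 13 and lower for 6. Among them APOA1 (-5.38, SE 0.22), FGG (at least 13.5-fold, adjusted p = 7.60e-05) and SERPINC1 (-2.94, SE 0.59, measured on 3 of 4 arrays labelled pregnant) were lower and ALB higher (2.79, SE 0.21). The plasma protein median was -0.43 (camera adjusted p = 0.757), and 0.71 with the strict filter on dim probes (adjusted p = 0.333; 0.333 to 0.856 over 23 alternatives). Candidates of the allantoic and amniotic membranes were higher for 1 of 9, KRT24 (3.54, SE 0.29), and lower for 5, among them the desmosomal genes PERP (-1.30, SE 0.27) and DSP (-1.15, SE 0.22). TP63 was at least 4.92-fold lower (adjusted p = 0.000120), and with normexp it gave -0.35 (adjusted p = 0.149; 1.05e-05 to 0.149 over 22 alternatives). The membrane candidates had a median of -0.78 (camera adjusted p = 0.210).

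Cytosolic ribosomal protein genes were higher for 6 of 35 and lower for 0 (0 and 0 adjusted over the list alone), with RPL30 at 0.82 (SE 0.23), RPS14 at 0.76 (SE 0.20) and RPL19 at 0.75 (SE 0.20). Their median was 0.41 (camera adjusted p = 0.0252, adjusted p = 0.667 with an estimated correlation). That call rested on the scaling, with 0.02 under median scaling (adjusted p = 0.262) and -0.08 without scaling (adjusted p = 0.538), where the named members lost their calls too. It also ended without the filter (0.0723), without labelled non-pregnant array 4 (0.0742) and without labelled pregnant array 1 (0.0653), within 0.00330 to 0.538 over 23 alternatives. Nuclear genes of the mitochondrial respiratory chain were lower for 26 of 34 and higher for 1 (SDHB, 0.62, SE 0.22), with UQCRFS1 at -1.73 (SE 0.25), NDUFS1 at -1.67 (SE 0.19), CYCS at -1.50 (SE 0.42) and NDUFB5 at -1.50 (SE 0.18). The respiratory median was -0.77 (camera adjusted p = 0.000968, adjusted p = 0.502 with an estimated correlation), and -0.24 with quantile normalization (adjusted p = 0.165; 5.90e-05 to 0.165 over 23 alternatives).

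Genes of the endoplasmic reticulum stress response, active in secretory cells, were lower for 13 of 19 and higher for 0, led by the kinase regulator TRIB3 (-5.73, SE 0.46), CRELD2 (-3.31, SE 0.35), SDF2L1 (-3.14, SE 0.30) and the chaperone DNAJC3 (-3.05, SE 0.27). Their median was -1.60 (camera adjusted p = 0.000492, adjusted p = 0.422 with an estimated correlation). Antioxidant enzymes were lower for 16 of 27 and higher for 4, with the glutathione enzymes GSR (-3.32, SE 0.31), GCLC (-3.03, SE 0.59, measured on 3 of 4 arrays labelled pregnant) and GPX4 (-2.94, SE 0.25) lower and GSTP1 (3.53, SE 0.34) higher. The antioxidant median was -1.28 (camera adjusted p = 0.0312, adjusted p = 0.442 with an estimated correlation). That call ended with quantile normalization (-0.87, adjusted p = 0.114), without scaling (0.0814), with the strict filter (0.0536), and without labelled non-pregnant array 2 (0.0563) or 4 (0.0520), within 0.00614 to 0.114 over 23 alternatives. Of 19 reference genes often used to scale expression, 9 were lower and 1 higher, including the transferrin receptor TFRC (-8.24, SE 0.51), HPRT1 (-2.38, SE 0.28), PGK1 (-1.82, SE 0.17) and B2M (2.81, SE 0.26). ACTB (-0.08, SE 0.25) did not pass, and ranged from -0.56 to 0.09 over 6 scalings and backgrounds, passing only without scaling (-0.56, adjusted p = 0.0461; 0.0461 to 0.809 over all 6). The reference gene median was -0.50 (camera adjusted p = 0.0632), and the list passed with normexp (adjusted p = 0.0185), without the filter (0.0154), without labelled non-pregnant array 4 (0.0463) and without labelled pregnant array 1 (0.0410) or 2 (0.0319), within 0.0154 to 0.134 over 23 alternatives.

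Of the 30 lists, 8 were higher and 12 lower in the arrays labelled pregnant by camera, and 0 were called with an estimated correlation, under which genes of a list that vary together count for less. Among other splits of the 8 arrays into 4 and 4, the 16 that exchanged 1 array of each group, and so kept most of the group difference, gave 14 to 21 called lists, and the 18 that exchanged 2 gave 1 to 9. By fry, 11 were higher and 17 lower. That test asks whether the genes of a list move on balance in 1 direction and does not set them against other genes.

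**Figure D2:**
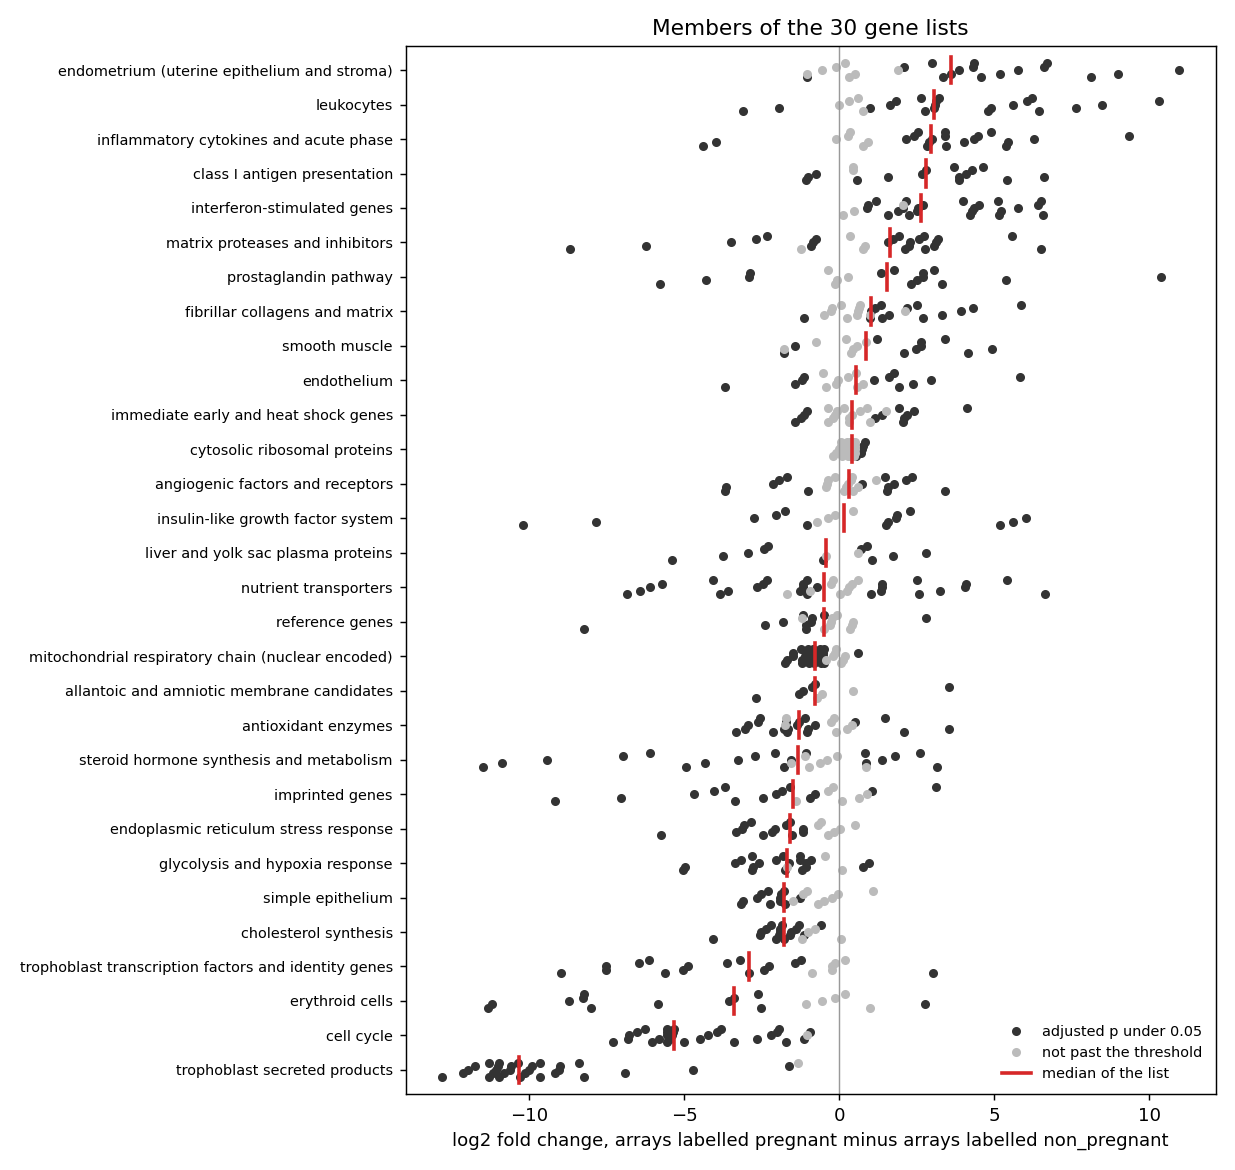
Difference of every tested member of the 30 gene lists (x axis, log2, labelled pregnant minus labelled non-pregnant), with dark points for members at adjusted p below 0.05, grey points for the others and a red bar at the list median. The medians run from -10.32 for secreted trophoblast products to 3.61 for endometrium, and those of angiogenic factors, the insulin-like growth factor system, immediate early genes and ribosomal proteins change sign under other scalings.

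The largest increases outside the lists on probes measured on all arrays began with APOD, a secreted lipid carrier (chromosome 1, 73197479 to 73197538), which averaged -5.55 ± 0.38 on the arrays labelled non-pregnant and 6.63 ± 0.14 on those labelled pregnant (SD, n = 4 each; 12.18, SE 0.22, adjusted p = 2.21e-08). The class II genes BOLA-DQB1 (10.36, SE 0.33) and BOLA-DQB (8.33, SE 0.25), the T cell receptor gene TCRA (8.52, SE 0.45), the lymphocyte antigen CD52 (8.05, SE 0.58), the neurotrophin receptor NTRK2 (8.42, SE 0.22) and ISLR (8.18, SE 0.72) followed. The largest bounds on that side were at least 3324-fold for the class II gene BOLA-DQA5, 2997-fold for MYOC, 2250-fold for the lymphocyte signalling regulator RGS1 and 1881-fold for the transporter ATP13A4 (adjusted p = 3.02e-07, 3.54e-07, 8.69e-07 and 1.18e-07). On the other side, SECTM1A (-9.37, SE 0.33) and SECTM1 (-8.997, SE 0.32), secreted and transmembrane proteins, joined the placental genes. The placenta-expressed gene PLET1 was at least 1926-fold lower and the proton pump subunit ATP6V1G3 at least 1160-fold lower (adjusted p = 6.32e-08 and 8.67e-08).

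The sex-linked genes differed within the arrays labelled non-pregnant, although every sample is labelled female. XIST, the RNA that coats the inactive X chromosome (chromosome X, 47216460 to 47216519), averaged -2.21 ± 4.12 on the arrays labelled non-pregnant and 4.90 ± 0.30 on those labelled pregnant (SD, n = 4 each; 7.11, SE 1.71, adjusted p = 0.00622). Its values on the arrays labelled non-pregnant were -3.50, -4.13, 3.89 and -5.09. The Y-linked gene DDX3Y was well above background on the other 3 of these arrays (-0.05, -0.25 and -0.11) and on 0 of 4 arrays labelled pregnant, so its probe fell short of the filter and was not tested. USP9Y (1.07, 0.49 and 0.26) and EIF2S3Y (-4.65, -4.02 and -2.85) were well above background on the same 3 arrays. The probes of the Y-linked genes EIF1AY and SRY and another probe of USP9Y were well above background on 0 of 8 arrays. Of 11 sex-linked genes written down, 7 were on the array and 2 were tested, XIST and ZFY (-1.52, SE 0.45, adjusted p = 0.0169, measured on 1 of 4 arrays labelled pregnant), which gave 0.03 with normexp (adjusted p = 0.903; 0.00343 to 0.903 over 22 alternatives). The ZFY probe is placed on chromosome X. It was also well above background on labelled non-pregnant array 3 (-5.06), where DDX3Y was not, so its signal did not follow that of DDX3Y.

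**Figure D3:**
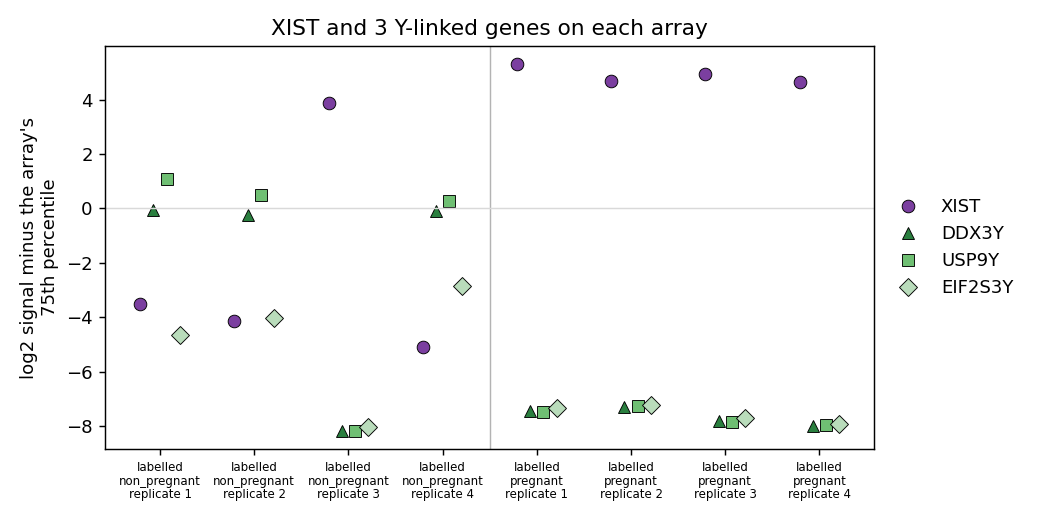
Signal of XIST, DDX3Y, USP9Y and EIF2S3Y on each of the 8 arrays (y axis, log2 signal minus the array's 75th percentile; 1 point per array). On the arrays labelled non-pregnant, XIST was 3.89 on array 3 and between -5.09 and -3.50 on the other 3, where DDX3Y was between -0.25 and -0.05.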

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

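The tests of the trophoblast, sex-linked and array 4 patterns were chosen only after the results were seen. So were the tests of other splits for the counts of genes, while those for probes and gene lists were fixed before the data were examined.

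Among 358 groups of 4 values (named genes and list medians), 25 held an array whose gap to the nearest other array took more of the group's range than Dixon's critical value for 4 values, against 17.9 by chance, which picks out about 1 in 20 groups. Of these, 17 lay in labelled pregnant array 4. In that array the gap took 0.905 of the range for MYOC, 0.923 for HOXD10, 0.830 for CLDN7, 0.865 for PMVK, 0.832 for NAP1L5, 0.868 for PGR and 0.913 for ESR1. The shares there were 0.924 for BOLA-NC1, 0.916 for BOLA, 0.895 for FBLN1, 0.858 for COL15A1, 0.901 for HBA, 0.896 for PTGER2, 0.917 for CXCL12, 0.925 for NDUFS1 and 0.902 for GSR. The median of the prostaglandin list stood apart in the same array by a share of 0.958. Single genes stood apart elsewhere: CD36 in labelled pregnant array 1 (0.917), ATP6V1G3 (0.924) and IRF1 (0.884) in labelled non-pregnant array 1, and RSAD2 (0.941) in array 2. GCLC (0.895) and ZFY (0.900) did so in labelled non-pregnant array 3, and B2M (0.838) and the erythroid median (0.896) in array 4. Outside the tested probes, the lowest of the 3 arrays with Y-linked signal lay above the highest array labelled pregnant by 7.04 for DDX3Y, 7.54 for USP9Y and 2.56 for EIF2S3Y (log2). These probes were well above background on 0 of 4 arrays labelled pregnant, so the gaps are to dim signals and are not measured folds.

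The first pattern is that placental transcripts were higher in the arrays labelled non-pregnant and uterine ones in those labelled pregnant. Scaling or brightness of the arrays is argued against, because the median of the secreted trophoblast products stayed at -8.80 or below over 6 scalings and backgrounds. Single arrays exchanged between the groups are argued against as well, with 0 arrays nearer to the other group. Tissue of a non-pregnant female alone is argued against for labelled non-pregnant arrays 1, 2 and 4. There the Y-linked DDX3Y was well above background (-0.05, -0.25 and -0.11), in a group where CSH2 averaged 6.98 and HBG 7.73. Array 3 of that group lacked DDX3Y signal, so the Y-linked values do not cover it. Its secreted trophoblast median of 6.54 lay among those of arrays 1, 2 and 4 (6.70, 6.38 and 6.11). These placental products argue against tissue of a non-pregnant animal alone on array 3 too. Fetal cotyledon as the main tissue is argued against for the arrays labelled pregnant. Their secreted trophoblast medians were -3.59, -5.82, -4.56 and -5.26, though 11 to 22 of the 30 members stayed well above background. An exchange of the group labels alone would still leave samples named fetal cotyledon, a placental tissue, under a non-pregnant label. A tissue other than the labels name, with or without exchanged group labels, stays open. All 8 arrays lay on the side that an exchange of the groups needs, for trophoblast and endometrium lists alike, but this restates the pattern and does not test it. Which of these applies, and whether pregnancy state itself has a part, was not tested, because the labels give no other tissue.

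The second pattern is XIST and Y-linked signal within the arrays labelled non-pregnant. Signal of the X-linked copy on the Y-linked probe is argued against, since 5 arrays had DDX3X but not DDX3Y well above background. A single RNA sample hybridised to all 4 arrays is argued against by the XIST range of 8.98 (log2). Tissue of both sexes among the arrays labelled non-pregnant stays open. All 8 arrays showed exactly 1 of XIST above 0 and DDX3Y well above background, which restates the pattern. Female tissue alone, as labelled, is argued against for labelled non-pregnant arrays 1, 2 and 4. There the Y-linked DDX3Y, USP9Y and EIF2S3Y were well above background and XIST was -3.50, -4.13 and -5.09. The design gives no groups by sex, so the source of the Y-linked signal was not tested.

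The third pattern is labelled pregnant array 4, which correlated at 0.943 to 0.951 with its group, against at least 0.977 among the other 3. It also lay nearer to the arrays labelled non-pregnant in HBA (1.37 against -1.24 to -0.98 in the other 3) and in the simple epithelium, steroid and erythroid medians (higher by 1.79, 1.16 and 0.95). RNA like that of the arrays labelled non-pregnant mixed in is argued against as the cause of the rise in HBA and the epithelial genes. The 18 secreted trophoblast genes well above background on array 4 allow a median share of at most 0.0612% (quartiles 0.0261% and 0.812%). The rise of HBA needs 0.979% and that of the epithelial genes 34.4%. For the steroid and erythroid medians the needed share was not worked out. Brightness or scaling of the array is argued against too, since signal level accounted for 2.07% of its squared deviations from the mean of the other 3, over 29562 probes well above background on all 4 arrays. Another part of the tissue, stage or animal stays open and was not tested, since the labels do not set this sample apart.

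The count of probes was 20563 in the real split and at most 1 in the other 34 of the 35 splits. The same holds for genes (8063, at most 0 in another split) and genes at least 2-fold apart (6180, at most 0), where in each case only 1 split, the real one, gave as many. These counts cannot exclude chance in the grouping. Every other split puts arrays of both groups on each side, so the group difference adds to the spread within a side and keeps the counts low. They show only that no other split of the arrays gave such counts of probes or genes. For the count of gene lists, with 20 in the real split and up to 21 in another, 3 of the 35 splits gave as many, so this test does not exclude chance. For lists the test is weak as well, because the 16 splits that exchanged 1 array of each group kept most of the group difference and gave 14 to 21 lists. The 18 that exchanged 2 of each group gave 1 to 9.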

How the results depend on the processing

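The fit without labelled non-pregnant array 3 and labelled pregnant array 4 was chosen after seeing the data, and the other alternatives before. Of the counts under alternatives, 247 stayed within 1.5 times the reported one and 7 did not. Of list results, 690 kept direction and side of the threshold, 42 lost the call, 16 gained it and 2 changed sign, and of named genes 3306 kept both, 15 lost the call and 5 changed sign. Probes differing ranged from 15766 (strict filter) to 27881 (no filter) against 20563. Without scaling, genes higher in pregnant numbered 2482. With an estimated correlation 0 lists were called (0 higher, 0 lower), where genes of a list that vary together weigh less. With treat, which tests against a 2-fold change, 3665 genes passed, 1859 higher and 1806 lower. Changes of sign were ZFY at 0.031 with normexp, the liver and yolk sac median at 0.71 with the strict filter, which tests fewer members, and the insulin-like growth factor list, 0.15 in the median but lower by fry. SSLP1 (-8.98) ranged from -9.77 to 1.502 over single arrays left out, with 1.20 or more without any array labelled non-pregnant, since another probe became its brightest. Leaving out each array in turn gave 18312 to 21068 probes, 7244 to 8239 genes, 5929 to 6376 genes at least 2-fold apart and 18 to 21 lists. The added fit gave 20629 probes, 8035 genes, of which 7462 were called in both fits and 7459 in the same direction, and 19 lists. For other changes of a call the cause was not tested. Signal over background limits the folds of dim probes: the secreted trophoblast median was -8.80 to -10.80 over scalings and backgrounds, and 312 called genes were well above background on no array labelled pregnant and 304 on no array labelled non-pregnant.

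The replicate number as a block gave 20208 probes (fixed) or 21224 (random) and 7831 or 8291 genes, with 20 lists in both. Whether the numbers pair the samples could not be decided. Deviations of same-numbered arrays correlated at 0.00908, 0.0753, 0.0498 and 0.155, not all above 0.1, against up to 0.0468, 0.0298, 0.0481 and -0.0639 for other numbers. The same-numbered value was the higher for numbers 2, 3 and 4. Arrays of equal number also shared a column of the slide, so a shared animal and a shared column cannot be told apart.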

Other observations

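The gene families, genes and comparisons of this part were all chosen only after the data were seen. Some families looked at went both ways: claudins (3 of 15 higher, 5 lower) and kinesins (9 of 29 higher, 13 lower). So did olfactory receptors (5 of 25 higher, 7 lower) and DNA methyltransferases with TET enzymes (1 of 6 higher, 2 lower). HOX genes, which give cells their position along the body, were higher in the arrays labelled pregnant for 17 of 22 tested genes, with a median of 3.55 (2.65 to 3.71 over 6 scalings and backgrounds). Beside HOXD10, HOXA5 differed by 5.19 (SE 0.25, n = 4 per group), HOXA3 by 4.87 (SE 0.55) and HOXA4 by 3.44 (SE 0.34). The only member called lower, HOXA13 (at least 2.06-fold, adjusted p = 0.0231), was well above background on 0 of 4 arrays labelled pregnant, and its fitted difference changed sign over the scalings and backgrounds. Class II histocompatibility genes, which present antigen to helper T cells, were higher for 9 of 9 (median 5.96, 4.43 to 6.12 over the scalings), though their probes can share signal between near-identical copies. Complement genes were higher for 14 of 17 and lower for 0 (median 3.29, 2.58 to 3.55), with C3 at 7.57 (SE 0.48), CFI at 7.30 (SE 0.70, measured on 3 of 4 arrays labelled non-pregnant) and C1S at 5.83 (SE 0.32). Of 8 killer lectin receptors and granzymes of cytotoxic lymphocytes, 7 were higher and 1, KLRB1 (-2.38, SE 0.69, measured on 1 of 4 arrays labelled pregnant), was lower (median 4.07, 1.70 to 4.23).

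Subunits of the vacuolar proton pump, which acidifies lysosomes and secretory vesicles, were lower for 17 of 22 and higher for 3 (median -1.54, -2.02 to -1.18 over the scalings). ATP6V1B2 differed by -3.46 (SE 0.20) and ATP6V1A by -2.69 (SE 0.19), while ATP6V0E2 (2.52, SE 0.20), ATP6V1G2 (2.53, SE 0.20) and ATP6V1E2 (3.49, SE 0.34, measured on 2 of 4 arrays labelled non-pregnant) were higher. The difference of ATP6V1E2 ranged from 1.65 to 3.65 over the 6 scalings and backgrounds. Histone genes were lower for 19 of 31 and higher for 1 (median -1.62, -2.11 to -0.82), with H2BC19 at -3.94 (SE 0.27) and H1-3 at -3.08 (SE 0.44). Secreted antagonists of WNT signalling went both ways, 4 of 10 higher and 3 lower, and their median of 0.14 changed sign over the scalings (-0.34 to 0.31). DKK4 (-11.27, SE 0.46) and DKK1 (-9.30, SE 1.53), each measured on 3 of 4 arrays labelled pregnant, were lower, while SFRP4 (8.90, SE 0.69, measured on 1 of 4 arrays labelled non-pregnant) and DKK3 (5.65, SE 0.24) were higher. The difference of SFRP4 ranged from 5.29 to 9.06 over the 6 scalings and backgrounds. In labelled pregnant array 4, DKK1 stood at 2.64 against a mean of -4.30 in the other 3.

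Trophoblast transcripts stayed measurable in the arrays labelled pregnant, to a different extent in each. On arrays 1 to 4, 22, 11, 21 and 18 of the 30 secreted products were well above background, and the list median was -3.59, -5.82, -4.56 and -5.26. The lowest signal among probes well above background was -7.45, -6.06, -7.82 and -7.66 on these arrays. The count of 11 on array 2 can therefore depend in part on its lower sensitivity. CSH2 stood at -0.03, -2.95, -0.37 and -2.29 and PAG2 at -1.07, -5.20, -1.91 and -4.20, while HBG stayed between -3.89 and -3.28.

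Labelled pregnant array 4 lay above the mean of the other 3 by 1.79 in the median of the simple epithelium list, by 1.16 for steroid hormone genes and by 0.95 for erythroid genes. It differed by -1.56 in the median of inflammatory genes, by -1.56 for trophoblast transcription factors, by -1.33 for leukocyte genes, by -1.04 for class I genes and by -1.01 for immediate early and heat shock genes. Retinoic acid hydroxylase CYP26A1 stood at 6.04 there against -0.58, and the epithelial secretory gene AGR2 at 1.92 against -4.55.

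The first principal component held 82.4% of the variance over all tested probes and separated the groups, and the second held 6.39%. The median difference between spots of 1 probe on 1 array was 0.0774 to 0.108, that between arrays of a group 0.193 to 0.524 and that between groups 0.863 to 1.21 (log2, 5811 probes).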
